A study of Rattus norvegicus with 6 samples.

How the data were processed

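The series holds 6 RNA libraries of the rat PC12 line, 3 controls and 3 from cells given 200 μM Sal for 24 h, per the labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a directional kit. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3, aligned with HISAT2 2.0.4, counted per gene with HTSeq 0.9.1 and compared with edgeR, its version not stated. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here.

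The deposited table gives, for 22714 rows with the biotype protein_coding, raw counts per library, per the file headers, and all tests here were run on those counts. It also gives log2 values that the file headers call normalized counts. These deposited log2 values were recomputed from the counts as edgeR log2 CPM with TMM factors and a prior count of 0.25, with a largest deviation of 4.97e-14. No fold changes or p-values of the authors' own comparison were found in the table as analysed, so there was no comparison of theirs to describe. Overlapping genes carry the coordinates of 1 merged locus, and 2280 of the genes share a locus with a gene on the other strand. Locus length therefore includes introns and, for such genes, the neighbour.

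Total counts per library ran from 118273 to 316488, and the median count of a tested gene in a library was 17. A count of 3 corresponded to 9.48 to 25.4 CPM over the 6 libraries. A gene with no count in a group was given a fold against a floor of 3 counts over that group. That fold leaves out the counting error of the other group, so the lower limit of the exact 95% interval lies below it. A gene with 1 to 3 counts was given a ratio with an exact 95% interval. These intervals cover counting error only. The number of genes at 2 counts was 2.35 to 2.75 times the number at 3 in each library, and the number at 4 was 1.45 to 2.26 times that at 3, so counts are not independent single events and the intervals are too narrow.

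The comparison was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter by group, a robust quasi-likelihood fit and its F test, two-sided, with Benjamini-Hochberg adjustment over the 2873 genes tested and a threshold of 0.05. The common dispersion was 0.138. Where a text gives an edgeR adjusted p or an adjusted p for a gene, it is from this test. Levels are TMM-normalised CPM, as mean ± SD of 3 libraries. Groups were taken from the labels. The labels do not state that replicates were independent cultures, and no block was used, since a shared replicate number is no pairing by itself.

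The comparison, the alternatives, 34 gene lists and the rule for naming genes were written down before the data were examined, except for 3 alternatives added later. The lists cover the subjects of the series title, catecholamine and neuronal genes, stress responses, growth and metabolism, and markers of other cell types. Each list was counted by members tested, risen and fallen over all genes, and adjusted over the list alone. The 26 lists with at least 5 tested members were also tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over lists. Named genes are the 10 largest rises and the 10 largest falls among genes that passed, whose groups did not overlap and whose mean was at least 5 CPM, a fixed set whatever its result, and up to 4 members with the smallest p per list. The fixed set also held Map1lc3b, which was not found by that symbol in the table as analysed. Other list members are named only to complete a count, namely Atp6v1b2, Asns, Eprs and Rpl3. Some genes that the rule selects are not reported here, while counts over lists include them. Shares of counts were compared with an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

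Alternatives were DESeq2 size factors, upper-quartile factors or library size alone in the same fit, no filter, a filter at a mean of 1 CPM, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each of the 6 libraries in turn, a threshold of 0.01, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Those added after the data were seen were leaving out the ribosomal RNA-like and mitochondrial rows, thinning each library at random to the smallest total, and leaving out genes that share a locus with a gene on the other strand. The alternatives planned for a table without counts did not apply. List medians were also set beside those of 10000 random lists matched on locus length within a window of 100 genes, a step chosen after the length trend was seen.

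The fit was tested on simulated counts for Sal against control, with the means and library sizes of the 2873 tested genes. It recovered 9 of 67 genes changed 2-fold (13.4%), 39 of 67 changed 4-fold (58.2%) and 59 of 66 changed 8-fold (89.4%), with 5 false calls among 112 (4.46%). Changes near 2-fold were thus mostly missed in this simulation. It changed far fewer genes than were called in the data, with directions drawn at random. It also drew counts independently, without the excess at 2 and 4 counts. Its shares recovered and falsely called therefore need not carry over to the data.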

Results

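RNA was measured in PC12 cells, a rat pheochromocytoma line of adrenal chromaffin origin that is widely used as a model of dopaminergic cells. The cells had been exposed to 200 μM Sal for 24 h or kept as controls, with 3 libraries per group. Sal is read here as salsolinol, the catechol isoquinoline formed from dopamine and acetaldehyde that the series title names. Per the title, the study concerns RNA m6A methylation, YAP1, autophagy and the death of dopaminergic cells, so the only comparison of the design, Sal against control, was described with those genes first. The table holds 22714 protein-coding genes, of which 9234 had no count in any library. Total counts assigned to these genes were low, at 316488, 295941 and 241013 in the controls and 174457, 118273 and 121987 with Sal. They do not give the number of reads sequenced. A gene at 3 counts therefore corresponded to 9.48 to 12.45 CPM in the controls and to 17.2 to 25.4 CPM with Sal. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Positions are those of the deposited table, on a build not given in the sources used here.

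**Figure D1:**
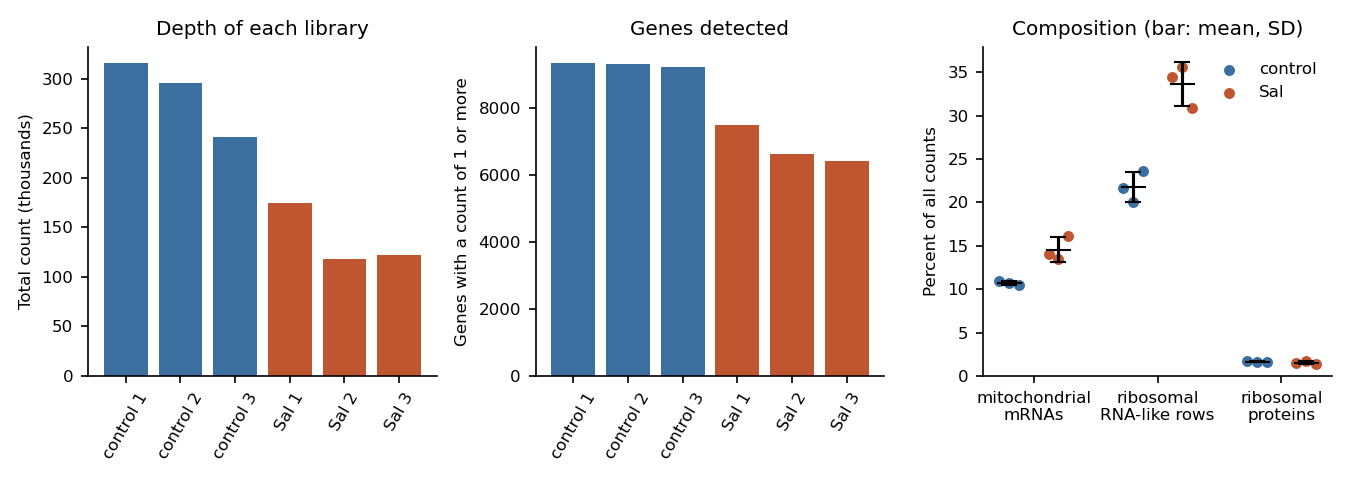
Total count and genes with a count in each of the 6 libraries, and the percent of all counts in 3 classes of rows, with points for libraries and bars for the mean and SD of 3. All 3 Sal libraries lay below all 3 controls in total count and genes detected and above them in the shares of mitochondrial mRNAs and of ribosomal RNA-like rows.

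Sal-treated cells differed from controls in a large part of the measurable transcriptome. The gasdermin gene Gsdma had 2 counts over the 3 controls and 1107 over the 3 Sal libraries, which is 1569 times the control level with a 95% counting interval of 433 to 12970. The RNA methyltransferase gene Bcdin3d rose from 8.34 ± 8.38 to 7952 ± 594 CPM (SD, n = 3 per group; log2 fold change 9.71, SE 0.39, edgeR adjusted p = 1.74e-13). Huwe1, an E3 ubiquitin ligase gene, had no count in the controls. It was 164-fold higher with Sal against a floor of 3 counts over the control group, with a lower 95% counting limit of 132-fold. Tmem219 (107-fold), Ccdc142 (86.0-fold), Cyb561d2 (40.6-fold), Mb21d1 (36.8-fold), Foxa3 (33.1-fold), Lrr1 (27.4-fold) and Asb16 (26.4-fold) also rose from no control count, against the same floor. Their lower 95% counting limits ran from 20.1-fold (Asb16) to 85.4-fold (Tmem219). Mb21d1 encodes the cytosolic DNA sensor cGAS and Foxa3 a forkhead transcription factor. All 10 rises started from under 20 CPM in the controls. Genes called higher from there more often had a tail-to-tail or overlapping gene on the other strand (61.8%) than tested genes not called (44.7%). The 10 genes are alone at their loci, but that leaves open a neighbour within 5 kb, which the 61.8% also counts. Whether reads of nearby genes contribute to these rises was not tested gene by gene.

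The 10 largest falls were all in genes with no Sal count, so that their folds are lower bounds too, from at least 14.6-fold to at least 24.4-fold lower. The 10 were the cytoskeletal linker genes Macf1, Syne1 and Tln2, the netrin receptor gene Unc5c, the tetraspanin gene Tspan18 and the dominant-negative helix-loop-helix gene Id3. The others were the GTPase-activating protein gene Arhgap21, the neuron navigator gene Nav2, the kinase gene Oxsr1 and the transcription factor gene Rfx7. Macf1 fell from 202 ± 56.9 CPM (chromosome 5, 144830885 to 145151309), Unc5c from 182 ± 62.5 CPM and Id3 from 145 ± 10.1 CPM (SD, n = 3). Of the 10, 9 lie in loci of 56.3 kb or more, the exception being Id3 at 1.59 kb. Of the 10 largest rises, 1 (Huwe1, 127 kb) did.

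Of 2873 genes with enough counts to test, 877 passed an edgeR adjusted p of 0.05, 356 higher and 521 lower with Sal (40.6% higher). Among the tested genes, 1360 (47.3%) had groups that did not overlap, against 10% by chance for 3 libraries against 3. The split between directions depended on the scaling. With library size alone in place of TMM factors, 220 genes were higher and 789 lower (21.8% higher), and the median log2 fold change of the tested genes shifted by -0.45. All changes are therefore relative to the TMM scaling. The 50 genes with the most counts held 42.2% ± 1.20 of control counts and 58.6% ± 0.952 of Sal counts (SD, n = 3; exact permutation p = 0.1), a difference of 16.4 percentage points that fell to 6.81 without the ribosomal RNA-like and mitochondrial rows. Correlations of log2 CPM between libraries were 0.833 to 0.841 within the controls, 0.699 to 0.744 within Sal and 0.314 to 0.369 between groups. Of the genes called lower, 71 had no Sal count and 139 had 1 to 3.

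Yap1, the transcriptional coactivator of the Hippo pathway, was nearly lost from the Sal libraries. It fell from 188 ± 41.6 CPM in the controls (51, 73 and 61 counts) to 8.72 ± 1.62 CPM with Sal (1 count in each library; SD, n = 3 per group; edgeR adjusted p = 1.73e-04). With only 3 Sal counts in all, the control level was 21.8 times the Sal level with a 95% counting interval of 7.33 to 106.5. The gene (ENSRNOG00000005933, chromosome 8, 6138909 to 6202218, minus strand) has no neighbour at its locus. The strand setting of the counting is not given in the sources used here. Having no neighbour therefore does not settle whether the counts of Yap1 come from its own strand. The locus length of 63.3 kb puts Yap1 among the 20% of genes with the longest loci, of which 243 fell and 18 rose. Amotl2, an angiomotin that binds YAP1 and is also a target gene of it, fell from 613 ± 64.6 to 275 ± 48.1 CPM (log2 fold change -1.15, SE 0.29, edgeR adjusted p = 0.00451). Of the 6 tested genes of the Hippo pathway core, these 2 fell and none rose (0 and 2 adjusted over the list alone). The others included the tumour suppressor Nf2 (log2 fold change -1.16, adjusted p = 0.204) and Amotl1 (-1.63, adjusted p = 0.12). Of 5 tested YAP/TAZ target genes, 2 fell, Amotl2 and the RNA-binding protein gene Rbms3, and none rose (2 fell adjusted over the list alone). Rbms3 had no Sal count and was 7.88-fold lower against the floor of 3 counts (lower 95% counting limit 6.23-fold). The camera test did not place either list apart from other genes (Hippo core adjusted p = 0.265, YAP/TAZ targets adjusted p = 0.162).

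Among the m6A genes, the methyltransferase gene Mettl3 rose and the writer-complex gene Zc3h13 fell. Mettl3 (ENSRNOG00000013111, chromosome 15, 32520600 to 32531328) went from 88.4 ± 58.9 CPM to 381 ± 40.3 CPM (SD, n = 3 per group; log2 fold change 2.09, SE 0.43, edgeR adjusted p = 0.00115). Its highest control library held 56 counts and the others 20 and 15, against 55, 42 and 37 counts with Sal. As for Yap1, the strand that these counts come from is not settled. Zc3h13 had 24, 24 and 21 control counts and none with Sal, at least 8.12-fold lower, and its locus of 64.7 kb is among the same longest 20%. Of the 7 tested writers, erasers and readers, these 2 changed (1 rose and 1 fell adjusted over the list alone). The list's median log2 fold change was 0.31 and its camera adjusted p was 0.748, but the sign of the median is not settled. It was negative with library size alone (-0.15), DESeq2 (-0.45) and limma-voom (-0.26), without a filter (-0.11) or at 1 CPM (-0.10), and without Sal replicate 1 (-0.23) or 2 (-0.48), and 0.82 without control replicate 3. The second methyltransferase subunit Mettl14 (log2 fold change 0.31, SE 0.85), the demethylase Alkbh5 (1.18, SE 0.84) and the reader Ythdf1 (-0.27, SE 0.78) did not pass the test. Wtap, Fto, Ythdf2 and Ythdf3 had 18, 37, 5 and 18 counts over the controls and were too low to test.

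**Figure D2:**
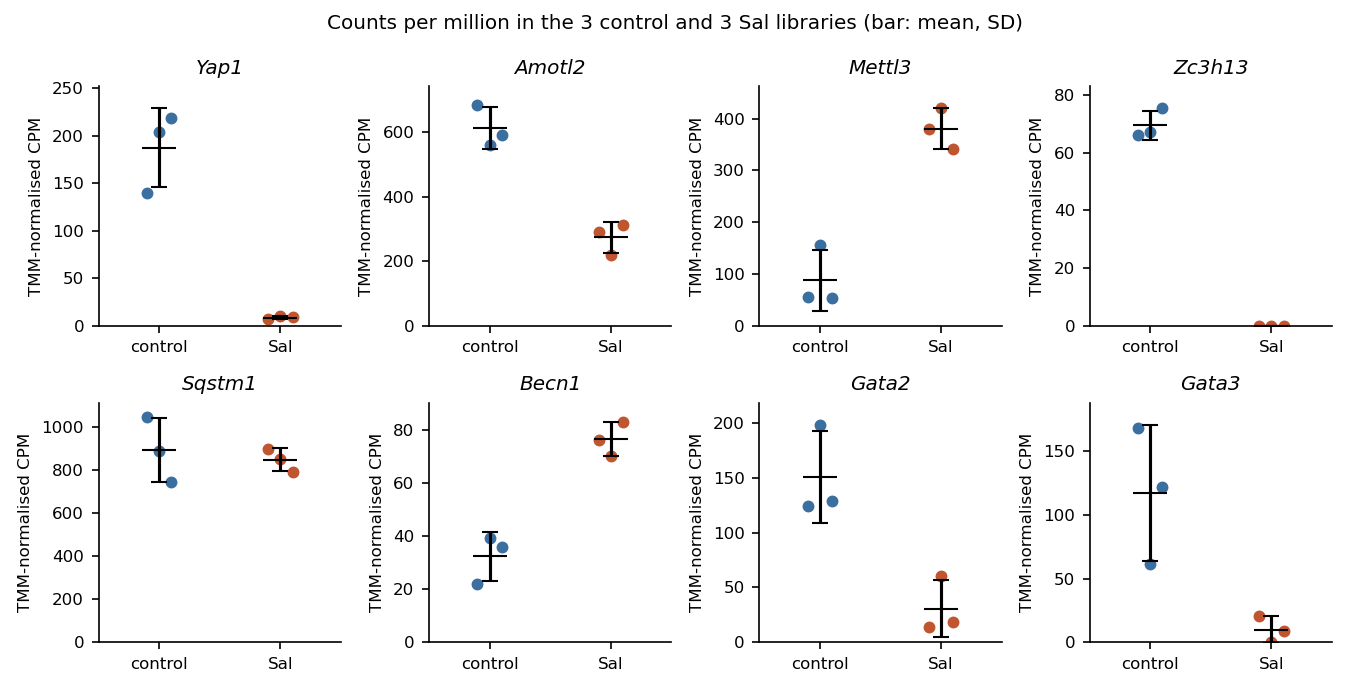
TMM-normalised CPM of 8 genes in each library, with the mean and SD of 3 libraries per group. Yap1, Amotl2, Zc3h13, Gata2 and Gata3 were lower with Sal and Mettl3 was higher, each past the test, while Sqstm1 and Becn1 did not pass it.

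Core autophagy genes showed little change that the depth could resolve. Of 10 tested members, only the protease gene Atg4d rose (22.7 ± 9.44 to 93.8 ± 22.1 CPM, SD, n = 3, edgeR adjusted p = 0.0307), none fell, and none passed when adjusted over the list alone. The Atg4d call was lost under 10 of its 16 alternatives, among them limma-voom. The autophagy receptor Sqstm1 was among the better measured genes, at 894 ± 150 CPM in the controls and 848 ± 53.5 CPM with Sal (log2 fold change -0.08, SE 0.24, edgeR adjusted p = 0.835). Becn1 was at 32.3 ± 9.07 and 76.4 ± 6.33 CPM (log2 fold change 1.23, SE 0.68, edgeR adjusted p = 0.182), and the LC3-family gene Gabarap at 61.7 ± 18.1 and 154 ± 67.2 CPM (adjusted p = 0.0763). The camera adjusted p of the list was 0.665, with a median log2 fold change of 0.16 whose sign is not settled. It was negative with library size alone (-0.29) and DESeq2 (-0.63), without a filter (-0.76) or at 1 CPM (-0.75), and without control replicate 3 (-0.25) or any of Sal replicates 1 (-0.13), 2 (-0.09) and 3 (-0.04).

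Of 18 tested lysosome genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). The lysosomal transcription factor gene Tfe3 went from 9.2 ± 11.4 to 113 ± 20.5 CPM (log2 fold change 3.47, SE 0.84, edgeR adjusted p = 0.00398) and the proton-pump accessory gene Atp6ap1 from 195 ± 11.98 to 429 ± 49.8 CPM, a call lost under 4 of its 17 alternatives. The cholesterol exporter gene Npc1 also rose, though its call was lost under 10 of its 15 alternatives, and the proton-pump subunit Atp6v1b2 fell. The list's camera adjusted p was 0.111 and its median log2 fold change 0.82. It passed with limma-voom (adjusted p = 0.0423) and not with DESeq2 (adjusted p = 0.294), its camera adjusted p ranging from 0.0331 to 0.43 over the alternatives. Of 8 tested genes of iron homeostasis and ferroptosis, 3 rose and none fell (4 rose adjusted over the list alone), and the list's camera adjusted p was 0.111. They were the phospholipid-remodelling gene Lpcat3 (39.7 ± 9.25 to 389 ± 151 CPM, edgeR adjusted p = 1.88e-05), the ferritin heavy chain gene Fth1 (269 ± 31.2 to 604 ± 160 CPM) and the ferritinophagy receptor gene Ncoa4 (32.8 ± 14.1 to 135 ± 66.2 CPM). The Fth1 and Ncoa4 calls were lost under 3 and 7 of 16 alternatives. Lpcat3, Fth1 and Npc1 share their loci with genes on the other strand, and the strand setting used in counting is not given in the sources used here, so their reads cannot be told apart from those of the neighbours.

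Mitochondrial transcripts took a larger share of the Sal libraries. Mitochondrially encoded genes held 10.7% ± 0.257 of control counts and 14.55% ± 1.45 of Sal counts (SD, n = 3 per group; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Of the 13 mitochondrial mRNAs, 7 rose and none fell (7 adjusted over the list alone), with a median log2 fold change of 0.78. The complex I genes ND3 (log2 fold change 1.43, SE 0.24), Mt-nd4 (1.23, SE 0.18), Mt-nd6 (1.19, SE 0.18) and Mt-nd5 (1.08, SE 0.16) had edgeR adjusted p of 1.77e-04, 6.5e-05, 9.51e-05 and 6.27e-05. This was the only 1 of 26 lists past the camera test (adjusted p = 0.00131). With an estimated correlation the call was lost (adjusted p = 0.43), and with library size alone it was lost too (adjusted p = 0.0748, median 0.32). Without genes that share a locus with a gene of the other strand the median was 0.45 (adjusted p = 0.0212, range over its camera alternatives 2.26e-07 to 0.43). Mt-nd6, the light-strand gene, held 46548 counts over the 6 libraries, against a median of 5180 and a maximum of 40542 over the 12 heavy-strand genes, and Mt-co1 held 3112. Mt-nd5 and Mt-nd6 overlap on opposite strands.

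Among nuclear genes of oxidative phosphorylation, the complex III subunit gene Uqcrq rose. It went from 135 ± 40.9 to 4945 ± 405 CPM (log2 fold change 5.19, SE 0.26, edgeR adjusted p = 7.19e-12). Of 18 tested, 4 rose and none fell (3 adjusted over the list alone). Cox6a1 and Cyc1 also rose, but lost their calls under 11 of 17 and 13 of 16 alternatives. The list's median log2 fold change was 0.25, turning to -0.20 with library size alone, -0.13 without a filter, -0.12 at 1 CPM, -0.05 in thinned libraries and -0.03 with DESeq2, and its camera adjusted p was 0.111. Of 46 tested cytosolic ribosomal protein genes, 6 rose and 1 fell (5 and 0 adjusted over the list alone). Rpl9 went from 6.63 ± 6.68 to 169 ± 52.2 CPM (edgeR adjusted p = 1.64e-04) and Rpl36 from 128 ± 99.5 to 455 ± 120 CPM (adjusted p = 0.00485), while Rpl3 fell (log2 fold change -0.89). The list's median was 0.24, or -0.21 with library size alone, with a camera adjusted p of 0.126, and its share of all counts was 1.65% ± 0.0788 in controls and 1.53% ± 0.186 with Sal (exact permutation p = 0.4), a difference of -0.116 percentage points that turned to 0.522 without the ribosomal RNA-like and mitochondrial rows (exact permutation p = 0.2). Of 13 tested ribosome biogenesis genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.274. The RNA polymerase I subunit Polr1a (control 13.8 times the Sal level, 95% counting interval 3.68 to 116) and the processing factor Rrp12 (12.9 times, 3.44 to 108) had 2 Sal counts each, and Nop58 and Ddx21 fell as well, each call being lost under 1 of 17 alternatives. The rows of LOC257642, described in the table as an rRNA promoter binding protein and treated here as ribosomal RNA-like, together with an unnamed row at the same locus held 21.8% ± 1.77 of control counts and 33.6% ± 2.51 of Sal counts (exact permutation p = 0.1).

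The transcription factor genes Gata3 and Gata2 fell. Gata3 went from 117 ± 53.4 to 9.98 ± 10.4 CPM (log2 fold change -3.34, SE 0.85, edgeR adjusted p = 0.00523) and Gata2 from 150 ± 41.6 to 30.8 ± 25.5 CPM (-2.34, SE 0.66, adjusted p = 0.0108). The Gata2 call was lost without control replicate 2 (adjusted p = 0.0542, range over its alternatives 0.00143 to 0.0542). They are among the 3 of 5 tested genes of catecholamine synthesis, storage and transport that fell, and none rose (3 fell adjusted over the list alone; camera adjusted p = 0.162). The vesicular transporter Slc18a2 was at 118 ± 34.2 and 73.0 ± 44.9 CPM (adjusted p = 0.408). Th, which encodes the rate-limiting enzyme of catecholamine synthesis, had no count in any of the 6 libraries, which allows up to 2.37 CPM over the pooled counts. None of the 21 chromaffin and dense-core vesicle genes in the table had enough counts to test, with 247 counts in all over the 6 libraries.

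Of 9 tested genes of neurite outgrowth and neuronal structure, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.895). The neurofilament heavy chain Nefh rose from 56.9 ± 23.1 to 254 ± 35.2 CPM (edgeR adjusted p = 0.00199), whereas the microtubule protein tau (Mapt) fell from 117 ± 32.2 to 12.8 ± 11.1 CPM and the adhesion molecule Ncam1 from 209 ± 47.7 to 29.2 ± 35.8 CPM. The loci of Mapt (94.1 kb) and Ncam1 (63.6 kb) are long and those of Nefh (9.99 kb) and Thy1 (4.82 kb) short, so these changes run along with the trend with locus length. Thy1 rose with a log2 fold change of 0.80, a call lost under 9 of its 17 alternatives. Of 6 tested Parkinson disease genes, 1 rose and 2 fell, Fbxo7 and Eif4g1 (1 and 2 adjusted over the list alone; camera adjusted p = 0.949). The calls of Fbxo7 and Eif4g1 were lost under 6 and 5 of 17 alternatives, limma-voom among them.

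Stress-response genes moved in both directions. In the integrated stress response, 2 of 17 tested genes rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.822). The methionyl-tRNA synthetase gene Mars (38.5 ± 16.4 to 432 ± 72.9 CPM, edgeR adjusted p = 5.02e-06), which shares its locus with a gene on the other strand, and the stress cytokine gene Gdf15 (88.0 ± 35.1 to 302 ± 137 CPM, adjusted p = 0.00522) rose. The amino acid transporter genes Slc7a5 (at least 10.1-fold lower, no Sal count) and Slc38a2 (168 ± 38.7 to 30.2 ± 28.0 CPM) fell, as did Asns and Eprs. Of 15 tested endoplasmic reticulum chaperone genes, P4hb (919 ± 25.4 to 1691 ± 134 CPM, adjusted p = 0.0041) and Calr (514 ± 20.5 to 989 ± 130 CPM) rose and none fell (2 rose adjusted over the list alone; camera adjusted p = 0.265). Both calls were lost under 3 of 17 alternatives, among them library size alone, where the list's median (0.45 with TMM) was near 0 (-0.002). In the NRF2 list, Fth1 was the only 1 of 10 tested genes that rose, and none fell (1 adjusted over the list alone; camera adjusted p = 0.334). In the cytosolic heat shock list, only the small heat shock protein Hspb1 rose of 10 tested (375 ± 73.9 to 813 ± 88.3 CPM, adjusted p = 0.00307), and none fell (1 adjusted over the list alone; camera adjusted p = 0.494; median 0.34, or -0.12 with library size alone). The Hspb1 and Slc38a2 calls were lost under 2 and 1 of 17 alternatives.

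Of 9 tested p53 targets, Ccng1 (148 ± 33.7 to 343 ± 188 CPM, edgeR adjusted p = 0.024) and Ei24 rose and none fell (2 adjusted over the list alone; camera adjusted p = 0.437). Their calls were lost under 8 and 9 of 17 alternatives. Of 4 tested apoptosis regulators, the anti-apoptotic gene Bcl2l1 fell from 119 ± 56.5 CPM to 1 count over the Sal libraries (1 fell adjusted over the list alone), the control level being 40.2 times the Sal level with a 95% counting interval of 7.08 to 1603. It shares its locus with a gene on the other strand. In the hypoxia and glycolysis list, Hif1a (235.5 ± 33.5 to 68.5 ± 49.9 CPM, adjusted p = 0.0119) and Ero1l fell and none rose of 14 tested (2 fell adjusted over the list alone; camera adjusted p = 0.981). That list's median was 0.05, and was negative under most alternatives, among them DESeq2 size factors (-0.04), library size alone (-0.41) and leaving out Sal replicate 1 (-0.91). The Ero1l call was lost under 8 of its 16 alternatives. The Hif1a call was lost without control replicate 2 and with limma-voom (adjusted p = 0.0602; range over its alternatives 7.58e-04 to 0.0602). Of 7 tested immediate early genes, the AP-1 genes Fos (40.4 ± 13.4 to 226 ± 76.6 CPM, adjusted p = 0.0016) and Fosl1 (20.2 ± 18.4 to 204 ± 28.0 CPM) rose and Egr1 fell (206 ± 23.5 to 31.3 ± 20.7 CPM, adjusted p = 0.00167), with the same 2 and 1 adjusted over the list alone (camera adjusted p = 0.665; median 0.18, but -0.28 with library size alone, -0.34 without a filter, -0.33 at 1 CPM, -0.02 with DESeq2 and -0.19 without Sal replicate 1). No metallothionein or zinc response gene had enough counts to test.

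Genes of proliferation and lipid synthesis that changed mostly fell. The replication factor Gins2 went from 457 ± 73.1 to 76.8 ± 55.5 CPM (edgeR adjusted p = 2.04e-04) and the ribonucleotide reductase subunit Rrm2 from 528 ± 110 to 222 ± 121 CPM. With them, 2 of 14 tested DNA replication genes fell and 1, Mcm7, rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.665). The Mcm7 call was lost under 12 of its 16 alternatives. Of 10 tested mitosis genes, 3 fell and none rose (3 adjusted over the list alone; camera adjusted p = 0.382). They were the phosphatase gene Cdc25b (2 Sal counts, control 18 times the Sal level, 95% counting interval 4.86 to 151), Top2a (3 Sal counts, 11.4 times, 3.79 to 56.3) and the spindle checkpoint kinase gene Ttk. All of the 3 genes that fell among 7 tested in fatty acid synthesis act in sequence from citrate, namely Acly (405 ± 53.6 to 162 ± 103 CPM), Acaca (239 ± 39.3 to 12.3 ± 21.3 CPM, adjusted p = 3.52e-04) and Fasn (209 ± 67.8 to 80.3 ± 18.3 CPM). None rose in that list (3 fell adjusted over the list alone; camera adjusted p = 0.162). The Acly and Fasn calls were lost under 3 and 6 of 17 alternatives, among them leaving out control replicate 3 or Sal replicate 1 for Acly (range of its adjusted p over all alternatives 8.09e-04 to 0.0576). In cholesterol synthesis, Fdps fell (467 ± 105 to 225 ± 61.6 CPM, adjusted p = 0.0207) and none rose of 7 tested (1 fell adjusted over the list alone; camera adjusted p = 0.665). Of 19 tested proteasome subunits, Psma5 and Psmd1 fell and none rose (0 adjusted over the list alone; camera adjusted p = 0.861). Their calls were lost under 5 of 17 and 8 of 16 alternatives, and Psmd1 shares its locus with Htr2b on the other strand. Among the genes of this paragraph, the calls of Rrm2, Fdps and Ttk were also lost under 2, 3 and 6 of 17 alternatives and that of Top2a under 3 of 16.

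Few inflammatory and interferon genes had enough counts to test. The 3 tested NF-kB and inflammatory genes, Rela, Nfkbia and Icam1, had edgeR adjusted p of 0.443, 0.519 and 0.911, so that none rose or fell (0 adjusted over the list alone). Of 3 tested interferon-stimulated genes Irf7 rose (14.5 ± 8.14 to 70.7 ± 22.7 CPM, adjusted p = 0.0334; 1 adjusted over the list alone), a call lost under 8 of its 13 alternatives. Of 8 tested mesenchymal and fibroblast markers, Tagln and Thy1 rose and Col5a1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.861), with a median near 0 (0.007, and negative under most alternatives, among them -0.08 with DESeq2 size factors, -0.45 with library size alone and -0.40 without Sal replicate 1). The Tagln call was lost under 9 of 16 alternatives and that of Col5a1 under 7 of 17. Of 4 tested adrenal cortex and epithelial markers, the keratin gene Krt8 rose (481 ± 86.6 to 804 ± 146 CPM, adjusted p = 0.0346), a call lost under 10 of its 17 alternatives, and Cdh1 fell, a call lost under 2 of 16 (1 and 1 adjusted over the list alone). No macrophage or leukocyte marker and no Schwann or glial marker had enough counts to test, with 70 and 16 counts over the 6 libraries.

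**Figure D3:**
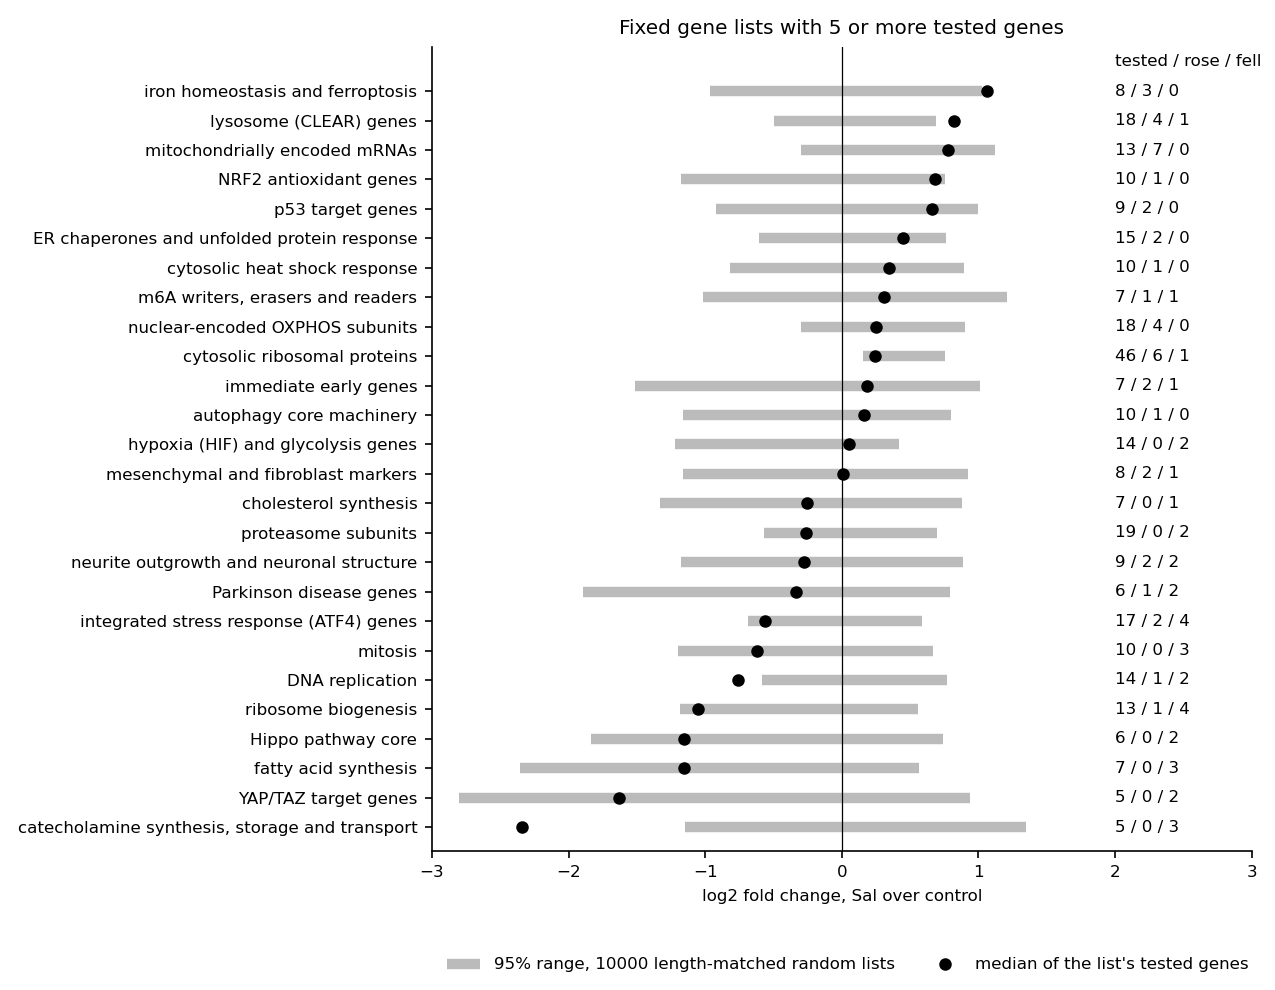
Median log2 fold change (x axis) of the tested members of the 26 gene lists with 5 or more of them (points), beside the 95% range of medians of 10000 random lists matched on locus length (grey bars), with the numbers tested, risen and fallen. The catecholamine list (-2.34, or -1.30 without Sal replicate 1) and DNA replication (-0.76, but -0.05 without Sal replicate 3, 0.20 when thinned and 0.10 with DESeq2) lay below their ranges and the lysosome (0.82, or 0.65 without Sal replicate 1) and iron (1.06, or 0.89 without Sal replicate 2) lists above theirs.

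Fold changes followed the length of the locus. Among 2387 tested genes alone at their locus, the median log2 fold change was 0.43 in the 20% with the shortest loci (312 to 6816 bp) and -1.80 in the 20% with the longest (56296 to 525439 bp). Among those with the shortest loci 92 genes rose and 32 fell, and among those with the longest 18 rose and 243 fell. The Spearman correlation across these genes, which are not independent replicates, was -0.48. Against random lists of tested genes matched on locus length, the median of the catecholamine list (-2.34) lay at percentile 0.1 and that of DNA replication (-0.76) at percentile 1.07, below their matched 95% ranges. The DNA replication median does not hold, being -0.05 without Sal replicate 3, 0.20 in thinned libraries and 0.10 with DESeq2, and that of the catecholamine list was -1.30 without Sal replicate 1. The medians of the lysosome list (percentile 99.1) and the iron list (percentile 97.8) lay above theirs, whose upper limits were 0.69 and 1.02. Without Sal replicate 1 the lysosome median was 0.65. The iron median was 0.89 without Sal replicate 2 and 0.94 without genes that share a locus with the other strand. These medians are under the upper limits of the main fit. Matched ranges were not drawn for these other fits, so whether either placement holds under them was not tested. These percentiles treat members as independent and are not adjusted over the 26 lists. With an estimated correlation none of the 4 lists outside their ranges passed camera. The adjusted p was 0.43 for each of the catecholamine, lysosome and iron lists and 0.83 for DNA replication. The iron list had a camera adjusted p of 0.45 without genes that share a locus with the other strand (range over its camera alternatives 0.0322 to 0.45). The Hippo core (percentile 12.1), YAP/TAZ targets (12.95), fatty acid synthesis (21.9), oxidative phosphorylation (38.65) and the mitochondrial mRNAs (77.3) lay within the range that genes of their length gave.

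**Figure D4:**
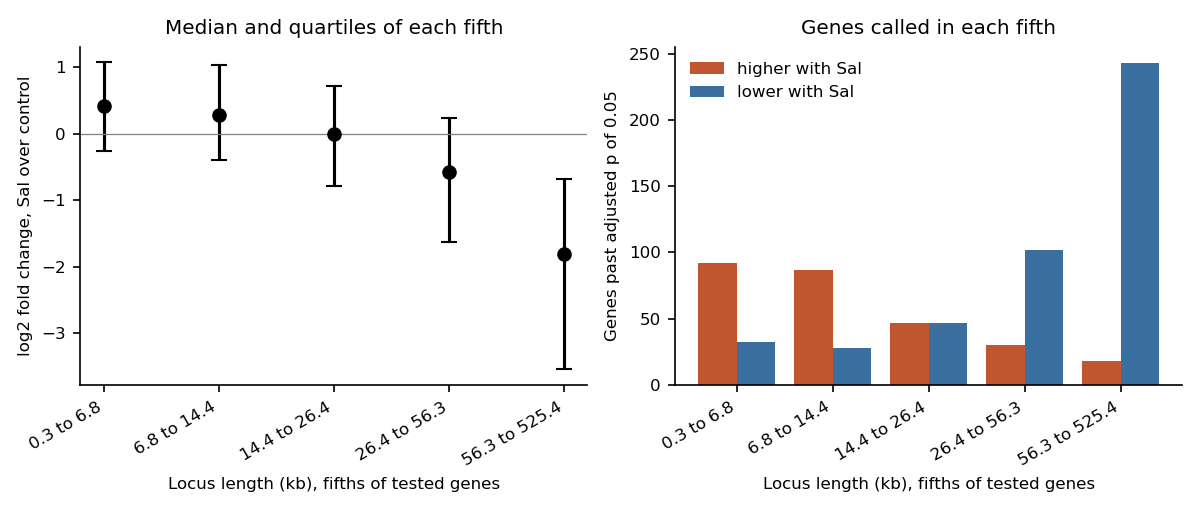
Median log2 fold change with quartiles (left) and the number of genes past an edgeR adjusted p of 0.05 (right) in 5 equal bins, by locus length in kb, of the 2387 tested genes alone at their locus. The median went from 0.43 in the shortest bin to -1.80 in the longest, where 243 genes fell and 18 rose.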

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

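Of the 90 named genes past the threshold, 54 kept their call at the same threshold of 0.05 under every other scaling, filter, tool, block, left-out library and set of rows that gave a value, 36 lost it under 1 or more, and 0 took the opposite sign. Yap1 (adjusted p from 1.05e-06 to 0.00187) and Mettl3 (1.47e-05 to 0.0144) kept theirs. Of the 54, Polr1a would not pass at 0.01 (adjusted p = 0.0119). The 877 genes past the threshold became 1505 with DESeq2, which tested 7469, 566 in thinned libraries, where 1665 were tested, and 508 at a threshold of 0.01. The 356 higher became 220 with library size alone, 571 with DESeq2 and 214 at 0.01. The 521 lower became 789 with library size alone, 934 with DESeq2, 310 in thinned libraries and 294 at 0.01. Leaving out 1 library gave 679 to 969 genes, 298 to 372 higher and 379 to 597 lower.

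In place of 1 list past camera there were 0 with library size alone, 3 without a filter, 3 with the filter at 1 CPM and 6 with DESeq2. There were 2 with limma-voom, 2 with the replicate block and 0 with an estimated correlation. Leaving out 1 library gave 1 to 6 (4 without Sal replicate 2, 6 without Sal replicate 3). There were 0 without the ribosomal RNA-like and mitochondrial rows, which removes that 1 list. Fry gave 10, but it tests each list against no change and not against other genes, so its count cannot be set beside these. The Hippo core and fatty acid synthesis passed without a filter, at 1 CPM and with DESeq2, and the YAP/TAZ targets with DESeq2 and without Sal replicate 3. The lysosome list passed with limma-voom, the block and without Sal replicate 2 or 3, the iron list and oxidative phosphorylation with DESeq2 and without Sal replicate 2 or 3, and the ribosomal proteins without Sal replicate 3. For the other settings the cause was not tested. Without those rows, the group difference in the ribosomal protein share was 0.522 percentage points (exact p = 0.2) in place of -0.116, and that of the top 50 genes 6.81 in place of 16.4. With all rows, a wider set of top genes gave 13.2.

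The replicate block gave 766 genes, 736 shared with the 877. The deviations of libraries with the same number correlated at -0.0295, -0.0185 and 0.0066, and 0 of 3 were best with their own number. These values gave no sign of pairing. With a median count of 17 per tested gene and library, they cannot exclude it. Depth limits genes under about 3 counts and, in the simulation, changes near 2-fold.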

Other observations

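The tests of Mt-nd6, of low depth and of silent genes, the thinning and the genes of the next paragraph were chosen only after the result was seen.

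Some genes outside the fixed lists, picked singly, changed from or to high levels. Ahnak went from 1636 ± 68.5 to 253 ± 68.2 CPM (log2 fold change -2.69, edgeR adjusted p = 3.82e-07), the microtubule protein gene Map1b from 1994 ± 153 to 359 ± 97.7 CPM (-2.48) and the dynein heavy chain gene Dync1h1 from 1846 ± 255 to 291 ± 117 CPM (-2.69). The cytokine receptor gene Lifr fell from 615 ± 110 to 6.69 ± 11.6 CPM (2 Sal counts in all). In the other direction, the lysosomal glycoprotein gene Creg1 rose with a log2 fold change of 6.90 (edgeR adjusted p = 1.22e-09) and Sdhaf2, an assembly factor of complex II, with 3.92. The proenkephalin gene Penk, expressed in chromaffin cells, was abundant in both groups (3383 ± 143 and 4202 ± 673 CPM, log2 fold change 0.31, adjusted p = 0.247).

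Counts of genes that share a locus were uneven between strands. Mt-nd6, the light-strand mitochondrial mRNA, held 8.99 times the median of the heavy-strand ones (6.23 to 21.8 per library). It also held more counts than the highest of them (46548 against 40542). The ratio is under the 10 times set for reads counted on the opposite strand. That cutoff was set after the result was seen, so falling short of it decides nothing. The other gene held more in 12 of 14 pairs of a housekeeping gene and a gene of the other strand at its locus. That is 85.7%, with an exact 95% interval of 57.2 to 98.2. An example is Phf14 (2132) over Ndufa4 (198), and counting on the opposite strand needs such an excess. Where several other-strand genes lay at a locus, the one with the most counts was taken, which favours the other gene. The interval treats pairs as independent, but Cox7b and Pgk1 share the partner Taf9b. Genes called higher from under 20 CPM had a tail-to-tail neighbour within 5 kb, or an overlapping gene on the other strand, in 61.8% of 110. The share was 44.7% of tested genes not called (Fisher's exact p = 5.34e-04 across genes, which are not independent). It was 26.9% among genes called lower and 24.8% over all genes. The ratio of 1.38 to genes not called lies between the bounds set for reads of the neighbour. Genes not called also exceeded all genes, so this ratio decides nothing on such reads. Head-to-head neighbours without overlap were at 20.9% against 17.1% (Fisher's exact p = 0.302). Counting on the opposite strand may therefore affect genes named here, and no biological explanation was tested.

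Catecholamine and chromaffin genes held few counts in all 6 libraries, 14 of 46 with none. Low depth hiding abundant transcripts is argued against, since the median gene's 95% upper limit was 10.8 CPM. That limit covers counting error only and leaves low levels open, and its cutoff was set after the result was seen. The median of 186 housekeeping genes alone at their locus was 56.4 CPM, which decides nothing on counting by strand, and the mesenchymal list held 2.67 times the counts of these lists (3693 against 1382), which decides nothing on cells in which they are silent. Both may contribute, and the identity of the cells cannot be told from these counts.

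Genes in long loci had lower fold changes, with a gap of -2.23 in median log2 fold change between the 20% of genes with the longest loci and the 20% with the shortest. Lower total counts of the Sal libraries are argued against, since 94.9% of the gap remained after thinning (-2.12). That gap is over the 1348 genes alone at their locus that were still tested. Thinning equalised totals but not the larger share of the top genes with Sal, so lower counts of the remaining genes are not excluded. The largest gap in the other 9 splits of the 6 libraries was 32.4% of the real one. Each of them parts the groups 2 to 1, so a group effect alone would leave a gap of about that size, and this test decides nothing on differences between single libraries. RNA fragmentation and an effect of Sal on long genes cannot be told apart, since the correlation with locus length (-0.48) needs transcript lengths to be read further.

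The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 877 genes, as many in 1 of 10 splits, and the highest other 0. It gave 1 list, as many in 4 of 10 splits, and the highest other 1.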
